A study of Mus musculus with 8 samples.

How the data were processed

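The series holds 8 arrays of RNA recovered with an ELAVL1 antibody from LbetaT2 cells, 4 from cells given GnRH for 30 min and 4 from cells given vehicle, all after 16 h without serum. Per the labels, 5 µg of antibody was bound to protein G beads, lysates were first cleared with beads and IgG, and the beads were washed 6 times before the RNA was extracted, labelled with biotin and hybridised. Groups and replicate numbers were taken from the sample titles, and columns were matched to samples by the sample number in the labels. All columns of the deposited tables belonged to these samples.

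The authors deposited a table of average bead signal intensity per probe, on a linear scale, neither normalized between arrays nor background-subtracted as far as its values show. Beside each signal stands a detection p-value, per the file headers. The authors also deposited a table of processed intensity values, whose normalization method is not given in the sources used here. Its values are linear, with array medians between 38.3 and 38.6, and its ranks followed those of the signal table on each array (Spearman's rho across probes at least 0.997), with no centring of genes. The scanner software and genome build are not given in the sources used here, so no coordinates are printed. Raw median signal per array ranged from 33.4 to 42.1, and 42.0% to 45.4% of probes were above background.

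Probes were named from the platform annotation, with symbols updated through the gene identifier or accession in a RefSeq gene table. Of 25697 probes 23978 had 1 gene symbol, 0 had several and 1719 had none, and 23962 matched the gene table by gene identifier. Each probe was tested on its own. The 10628 tested probes with a symbol covered 8076 genes, of which 1928 had more than 1 tested probe.

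Signals were background-corrected with normexp from the detection p-values, an offset of 16 was added, and the values were quantile normalized and put on the log2 scale (neqc in limma 3.58.1, R 4.3.3). Probes with a detection p below 0.05 on at least 4 of 8 arrays were tested, which left 11318 (44.0%). Groups were compared with lmFit and eBayes without a block, and p-values were adjusted with the Benjamini-Hochberg method at 0.05. With an offset of 50 the called probes' median log2 change was 1.51 in place of 1.75. Quantile normalization removes any difference in total yield between pull-downs, together with differences in array brightness. Without it the median of all tested probes shifted by 0.11 on the log2 scale, a shift in which yield and brightness cannot be told apart. Where a probe was not above background on any array of a group, a bound is given in place of a fold change. Such bounds hold for this processing only. The median SE of a log2 change was 0.18.

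Gene lists, 17 in number, were fixed before the data were examined. They were tested with camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 16 lists with at least 3 tested genes; the replication-dependent histone list had no gene on the array under the names used here. An estimated correlation and fry were alternatives. A list's median and mean were taken over its tested probes. Over-representation of called genes was tested with Fisher's exact test against all other tested genes.

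The rule for named genes was also fixed before the data were examined. It takes, among probes past the threshold whose 4 GnRH values all lie above or all below the 4 vehicle values, the 12 genes with the largest rise and the 12 with the largest fall, using probes with 1 gene symbol, the probe with the lowest p per gene and no placeholder names. Where fewer than 8 genes meet this in a direction, it takes the 8 genes with the lowest unadjusted p among probes of the same kind. It always takes Elavl1, Gnrhr, Lhb, Fshb, Cga, Egr1, Fos and Dusp1, and up to 4 members of each list with the lowest p.

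The fit and the list test were tried on simulated log2 values made from the 11318 probes of this comparison, with 200 probes changed in each of 20 simulations. The fit called 65.6% of probes raised by 1 on the log2 scale and 59.5% of those lowered by 1, 95.5% and 93.8% at a change of 2, 7.65% and 7.88% at a change of 0.5, and 0.0459% of unchanged probes. Lists of 30 probes shifted by 0.5 were called in 20 of 20 simulations and unchanged lists in 1 of 20. Probes were simulated as independent of each other, so these rates do not cover real lists whose members vary together. The rates for single probes also leave out background correction, normalization and any effect shared by the probes of an array. On the real arrays fewer probes had an unadjusted p below 0.05 than chance gives, so the rates may not hold there.

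The alternatives covered background correction and offset, normalization, the authors' processed values, the filter on dim probes, the variance model, array weights, replicate number as a block, sample number as a covariate, the probe used for a gene, the list test, and leaving out each library in turn. Runs of neighbouring sample numbers as a block, and lists without the immediate early genes, were added after the data were seen. Similarity of libraries in relation to sample number was tested only over pairs of a GnRH and a vehicle library, with sample numbers permuted within groups in all 576 ways, because subtracting the mean of 4 libraries lowers correlations inside a group (mean -0.314 over 12 pairs, against -0.00443 over 16 pairs across groups). Figures were drawn with matplotlib 3.10.9.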

Results

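RNA bound to ELAVL1 was measured in LbetaT2 cells, an immortalised mouse pituitary line of the gonadotrope lineage, the cells that make the gonadotropins. ELAVL1, also called HuR, is an RNA-binding protein that attaches to AU-rich and U-rich stretches of messenger RNA. After 16 h without serum the cells received gonadotropin-releasing hormone (GnRH) or vehicle for 30 min, ELAVL1 was pulled down from the lysates with its antibody, and the RNA that came with it was hybridised to an Illumina mouse bead array of 25697 probes. There were 4 GnRH and 4 vehicle libraries, 1 array each. The median raw signal per array lay between 33.4 and 42.1, and between 10802 and 11663 probes were above background (detection p below 0.05). The number of probes above background was 11184 ± 201 in the GnRH group and 11243 ± 471 in the vehicle group (mean ± SD, n = 4). The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of every value. RNA taken before the pull-down and control pull-downs were not analysed here, so each value is the amount of a transcript in the ELAVL1 pull-down.

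The design addresses which transcripts in the ELAVL1 pull-down differ in amount after GnRH. Transcripts of several immediate early transcription factors, Egr1, Egr2, Egr4, Fos, Fosb, Jun and Junb, were more abundant in the pull-down after 30 min of GnRH. Egr2 was 83.9-fold higher (log2 change 6.39 ± 0.12, SE), Fosb 53.3-fold higher (5.74 ± 0.20), Fos 19.7-fold higher (4.30 ± 0.27), Junb 16.8-fold higher (4.07 ± 0.42), Egr1 14.0-fold higher (3.80 ± 0.19) and Jun 10.1-fold higher (3.34 ± 0.17), each with 4 libraries per group. Egr4 was not above background on any vehicle array and reached a mean log2 signal of 11.73 ± 0.32 (SD, n = 4) after GnRH, at least 136-fold higher in this processing. Over other scalings its fitted log2 change went as low as 6.57, below that bound. No probe was lower after GnRH at the same threshold.

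In all, 30 of 11318 tested probes, from 27 genes, were higher after GnRH and 0 were lower (limma, Benjamini-Hochberg adjusted p below 0.05). One of the 30 probes has no gene name. At an unadjusted p below 0.05, 237 probes were higher and 92 were lower, against 566 expected by chance over both directions. Every one of the 30 probes had its 4 GnRH values above its 4 vehicle values, a separation that passing the test favours. Over all tested probes 1.53% were separated upward and 0.618% downward, where chance gives 1.43% of unchanged probes in each direction. The fitted log2 changes of the 30 probes ran from 0.96 to 7.36 with a median of 1.75, and by these 26 changed at least 2-fold and 12 at least 4-fold. They include 4 probes below background on every vehicle array, for which only a bound holds. The largest, that of Egr4, has a bound of 7.09. The lowest adjusted p among probes with a negative change was 0.445, for Pura (limma).

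The remaining genes among the 12 largest rises encode enzymes, an RNA-binding protein and further transcription factors. Zfp36, which encodes tristetraprolin, a protein that promotes decay of AU-rich transcripts, rose by 2.80 ± 0.19 on the log2 scale (SE, limma adjusted p = 3.88e-05). Sik1, a salt-inducible kinase, rose by 3.21 ± 0.41 (adjusted p = 0.00834, limma). Itpkc, an inositol trisphosphate kinase, rose by 2.03 ± 0.32 (adjusted p = 0.0293, limma), and its GnRH replicate 4, at a log2 signal of 9.64, stood apart from the other GnRH libraries, at 8.17 to 8.41. Npas4, an activity-induced transcription factor known from neurons, and Atf3, a stress-induced one, were not above background on any vehicle array. The GnRH libraries lay at least 6.89-fold higher for Npas4 (adjusted p = 4.65e-05, limma) and at least 2.95-fold higher for Atf3 (adjusted p = 0.0384, limma). Each bound sets the GnRH mean against the vehicle mean of the higher of the probe's own value and the lowest detected signal on that array. On the log2 scale the bound of Atf3 is 1.56, below the change of Rhob (1.80). The place of Atf3 among the 12 thus rests on its fitted change of 1.88. The call for Itpkc ended under 8 of its 24 alternative settings and that for Atf3 under 8 of 19, while those for Sik1 and Junb ended only with no filter on dim probes (adjusted p = 0.176 and 0.0738, limma).

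**Figure D1:**
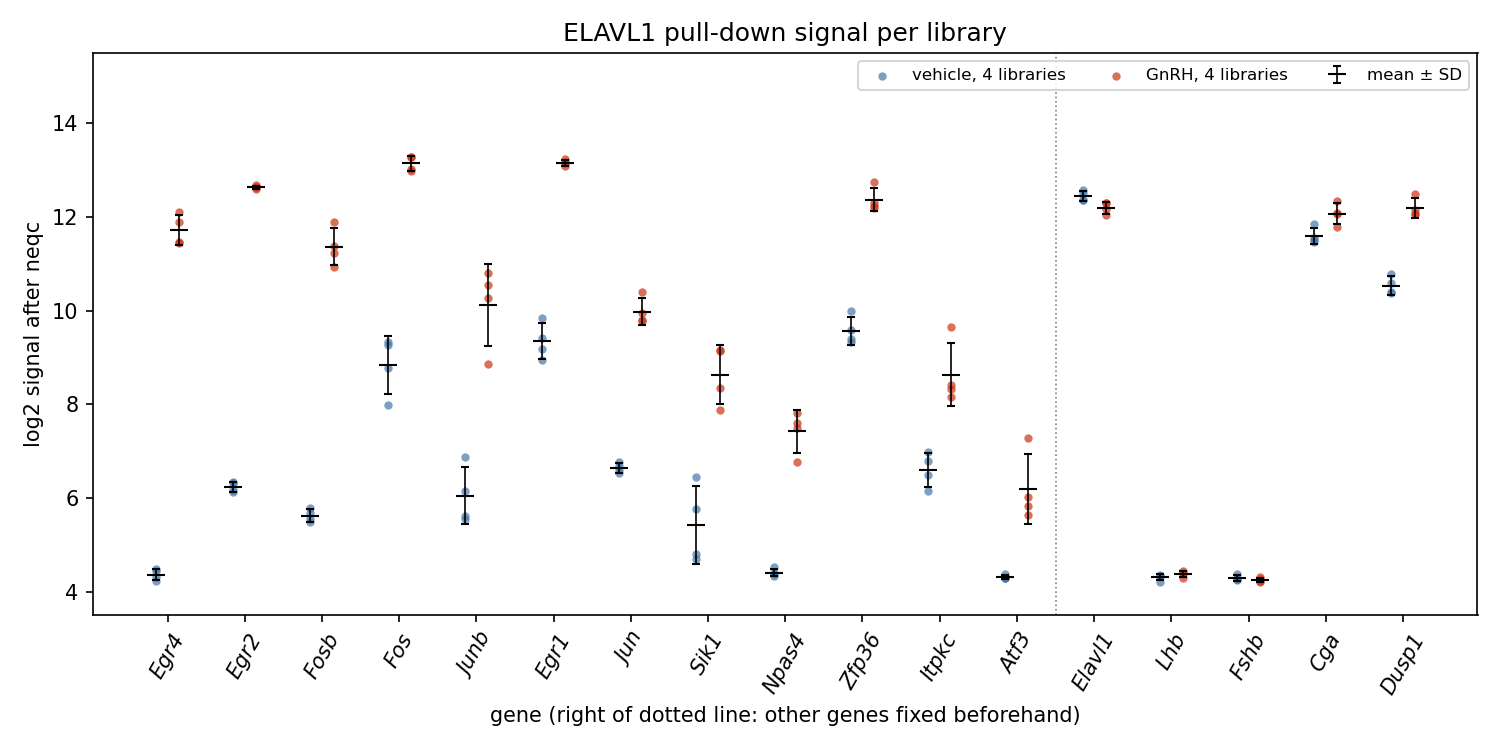
Log2 signal after background correction and quantile normalization (vertical axis) of the 12 genes with the largest rise and, right of the dotted line, of other genes fixed beforehand (horizontal axis), with points for the 4 vehicle and 4 GnRH libraries and bars for mean ± SD. The GnRH points of Egr2 lie near 12.64 and its vehicle points near 6.24, while Lhb and Fshb stay near the floor in both groups.

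The immediate early genes, which are transcribed within minutes of a stimulus without new protein synthesis, held most of the calls. Of 39 tested members 19 were higher and 0 lower, and 28 were higher when adjusted over the list alone. The list's median log2 change over its probes was 0.80, and 36 members had a positive and 3 a negative change. Its shift passed camera with a preset correlation (adjusted p = 3.90e-82) and also with an estimated one (adjusted p = 0.00139 with an estimated correlation). The share of called genes inside the list, 19 of 39, exceeded that outside it, 8 of 8037 (Fisher's exact test, two-sided, p = 1.08e-40). Besides the genes above, Btg2 (1.43 ± 0.17), Srf (1.38 ± 0.21), Klf6 (1.35 ± 0.18), Nfil3 (1.53 ± 0.20), Csrnp1 (1.62 ± 0.23), Rhob (1.80 ± 0.26), Ier3 (0.99 ± 0.17), Arc (0.96 ± 0.15) and Ccn1 rose (log2 change ± SE). Those genes other than Rhob were chosen for naming after their values were seen. The Ccn1 probe that passed was not above background on any vehicle array and was at least 1.58-fold higher, while a second probe, at 0.55 ± 0.13, did not pass (limma adjusted p = 0.445). A second Klf6 probe, at 0.99 ± 0.41, did not pass either (limma adjusted p = 1.00). Of these genes Btg2 alone stayed called in every alternative setting that tested it (23 of 23), while Csrnp1 stayed called in 21 of 24, Klf6 in 20 of 24, Nfil3 in 20 of 23, Rhob in 19 of 24, Srf in 17 of 24, Arc in 15 of 24, Ccn1 in 9 of 18 and Ier3 in 7 of 24.

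Feedback regulators of MAP kinase and calcium signalling were higher in part. Dusp1, a phosphatase that inactivates MAP kinases, rose by 1.65 ± 0.16 on the log2 scale (SE, limma adjusted p = 9.53e-04), and both probes of Dusp2, a related phosphatase, rose, by 1.00 ± 0.16 and 1.50 ± 0.24. The 2 Dusp2 probes stayed called in 11 of 22 and 14 of 23 alternative settings that tested them. Of 18 tested members 2 were higher over all genes tested and 4 adjusted over the list alone, which adds Dusp8 (0.80 ± 0.17) and Dusp6 (0.67 ± 0.18). The list passed camera with the preset correlation (adjusted p = 2.07e-05), and the call was lost with an estimated one (adjusted p = 0.0676 with an estimated correlation). None of the 38 tested components of GnRH receptor signalling passed, adjusted over the list alone or over all genes, and the list's camera adjusted p was 0.345. Its member with the lowest p was Adcy6, an adenylyl cyclase, at -0.35 ± 0.15 (limma adjusted p = 1.00).

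Among transcripts that the literature lists as ELAVL1 targets, 3 of 34 tested genes were higher, Fos, Dusp1 and Rhob, and the same number were higher adjusted over the list alone. Outside the list 24 of 8042 genes were higher (Fisher's exact test, two-sided, p = 1.86e-04). Without members of the fixed immediate early list, which does not hold Dusp1, the list held 1 called gene of 31, Dusp1 (p = 0.0988, same exact test). Bcl2 (0.47 ± 0.18) and Vegfa (0.72 ± 0.29) did not pass (limma adjusted p = 1.00 for each), and the other tested Bcl2 probes lay between -0.09 and 0.35. Vegfa, chosen for naming after its values were seen, had another probe at 0.13 ± 0.17. The list's median change was 0.04. It passed camera with the preset correlation (adjusted p = 0.0361), and the call was lost with an estimated one (adjusted p = 0.477 with an estimated correlation) and without the 3 members shared with the immediate early genes (adjusted p = 0.271). Among 38 tested RNA-binding proteins Zfp36 alone passed, over all genes and adjusted over the list alone, and the list's camera adjusted p was 0.345; the list's mean change was -0.01 and its median -0.08. Elavl1 itself stood at a log2 signal of 12.20 ± 0.13 after GnRH and 12.45 ± 0.11 in vehicle (SD, n = 4), a change of -0.25 ± 0.13 that did not pass (limma adjusted p = 1.00).

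Of 15 tested gonadotrope genes only Egr1 passed, over all genes and adjusted over the list alone, and the list's camera adjusted p was 0.153. Cga, the common alpha subunit of the glycoprotein hormones, stood at 12.07 ± 0.23 after GnRH and 11.60 ± 0.17 in vehicle (SD, n = 4), a change of 0.47 ± 0.16 (SE, limma adjusted p = 1.00). Lhb and Fshb, the beta subunits of the gonadotropins, were not above background on any array. Gnrhr, the GnRH receptor, had the highest signal on all 8 arrays, which quantile normalization sets equal, so its difference was read after median scaling, where it was -0.01 ± 0.15 (SE, limma adjusted p = 1.00). Secretory granule genes had no called member among 21, over all genes or adjusted over the list alone, with Vgf at 0.70 ± 0.21, Chga at 0.60 ± 0.19 and Scg3 at 0.49 ± 0.17 (limma adjusted p = 1.00 for each). Chga's other probes gave 0.74 ± 0.27 and -0.02 ± 0.24, and Rab3d stood at -0.25 ± 0.13. That list passed camera upward with the preset correlation (adjusted p = 0.0421), not with an estimated one (adjusted p = 0.269 with an estimated correlation).

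The unfolded protein response list had 0 called members of 25, and 2 were higher adjusted over the list alone. These were Ppp1r15a, the stress-induced phosphatase subunit GADD34, at 1.69 ± 0.30 (limma adjusted p = 0.0612 over all genes) and Herpud1, a component of degradation at the endoplasmic reticulum, at 0.86 ± 0.17 and 0.74 ± 0.18 for its 2 probes. Ppp1r15a also stood on the immediate early list. The shift passed camera upward with the preset correlation (adjusted p = 1.73e-04) and was lost with an estimated one (adjusted p = 0.463 with an estimated correlation). Translation factors had 0 called members of 46, over all genes or adjusted over the list alone, and a median change of -0.08, with Eif5a2 at -0.63 ± 0.26. The probes of Eif4e3 disagreed, at 0.36 ± 0.16, -0.18 ± 0.21 and -0.17 ± 0.20, those of Eef2 stood at -0.40 ± 0.18 and -0.16 ± 0.19, and those of Eif3a at -0.54 ± 0.27 and -0.02 ± 0.19. Translation factors passed camera downward with the preset correlation (adjusted p = 0.0421), not with an estimated one (adjusted p = 0.626 with an estimated correlation). Cholesterol synthesis genes had 0 called members of 20 and did not pass (camera adjusted p = 0.0724); Fdps stood at -0.36 ± 0.19 and Pmvk at 0.82 ± 0.24, with GnRH replicate 4, at 7.07, apart from the other GnRH libraries, at 5.99 to 6.16.

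Cell cycle genes (0 of 37), cytosolic ribosomal proteins (0 of 53) and oxidative phosphorylation subunits (0 of 67) had no called member, and their camera adjusted p-values were 0.331, 0.345 and 0.378. Markers of other cell types were seldom above background, which left 3 genes for other pituitary lineages, 5 for stroma and endothelium and 3 for blood. None of these passed, and their camera adjusted p-values were 0.463, 0.331 and 0.463. No gene of these lists or of the cholesterol list passed adjusted over the list alone.

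**Figure D2:**
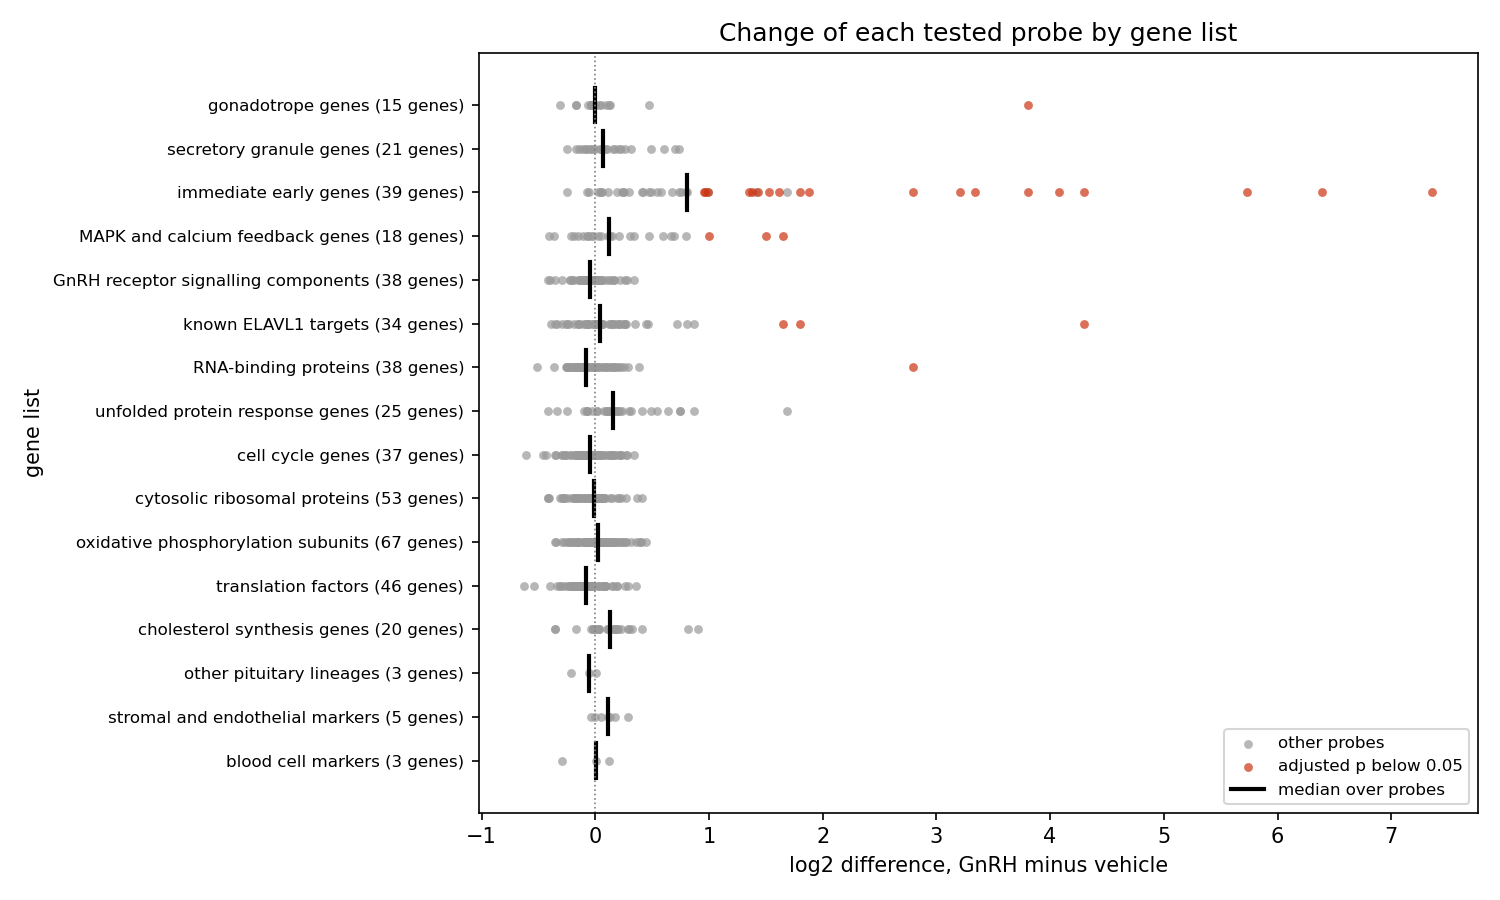
Log2 difference between GnRH and vehicle (horizontal axis) of each tested probe of the 16 tested gene lists (vertical axis, with the number of tested genes), with red points for probes past the threshold over all probes, grey points for the others and a black line at the median over probes. The immediate early genes have a median of 0.80, and no probe past the threshold lies below 0.

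On the falling side no gene passed, and the 8 with the lowest unadjusted p are given as values (limma). Pura, a nucleic acid binding protein, stood at -0.68 ± 0.17, Psmd6, a proteasome subunit, at -0.52 ± 0.14, Ccni at -0.64 ± 0.19 and Tars, the threonyl-tRNA synthetase, at -0.46 ± 0.14 (log2 change ± SE). Sox12 stood at -0.54 ± 0.17, Kbtbd7 at -0.44 ± 0.15, Zc3h11a at -0.47 ± 0.18 and Gopc at -0.41 ± 0.16. Adjusted p-values of these 8 genes ran upward from 0.445. Second probes gave -0.27 ± 0.19 for Psmd6, -0.18 ± 0.17 for Sox12 and -0.007 ± 0.16 for Tars, whose fall was thus not seen on its other probe. With array weights 4 probes passed as lower, Ccni, Pura, Yipf5 and 1 without a gene name, of which Yipf5 was chosen for naming after its value was seen. The count of higher probes fell from 30 to 18 without GnRH replicate 1, to 16 without GnRH replicate 2, to 17 without vehicle replicate 3 and to 14 with no filter on dim probes.

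Over the 16 pairs of a GnRH and a vehicle library, a fall in similarity with distance in sample number did not pass (r = -0.410 with the correlation of deviations from the group means, exact permutation test within groups, one-sided, p = 0.0868). Run first over all 28 pairs with all sample numbers permuted, the test had passed (r = -0.435, p = 0.0177), a value to which the centring of pairs within a group contributes. Sample numbers 1 to 3, 4 to 6 and 7 to 8, a division chosen after the correlations were seen, each hold both groups. Fitted as a block over all tested probes, they gave 45 higher and 0 lower probes, the 30 among the 45. The called probes' median log2 differences within the 3 runs were 1.79, 1.50 and 2.17, whose sign follows from the full separation of the groups on these probes.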

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

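The test with runs as a block, the test that needs RNA from before the pull-down and the tests of order, brightness and shared culture were chosen only after the patterns were seen, and those of order and brightness took this form after other forms had been run, a change that ended the call on the tested probes.

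The rise of 30 probes after GnRH was set against chance, processing and the pull-down itself. Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave as many probes, and the highest count among the other splits was 0. The smallest share these splits can give is 2.86%, so they argue against chance but cannot exclude it. In the other splits the strongly changed probes fall on both sides and widen the spread, which favours low counts there. Quantile normalization and the runs of sample numbers as the whole cause were argued against, since the called probes kept a median log2 difference of 1.89 without between-array normalization and 45 probes, the 30 among them, were higher with the runs as a block over all tested probes. The runs were read from these data, so the block takes up spread and favours calls. The gain from 30 to 45 is thus no evidence in itself. Each run holds both groups, so fully separated probes were likely to stay called. For a general gain of ELAVL1 targets in the pull-down, the known targets that are not immediate early genes had a median log2 difference of 0.17 without between-array normalization (95% bootstrap interval over 31 genes 0.07 to 0.27), beside 0.11 for all tested probes. In array signal these targets thus showed no gain near that of the called probes. The interval covers the spread between genes and not between arrays. A gain shared by all bound transcripts stays open, because no measure of yield apart from array signal was used. More of each transcript in the cells and more of it bound cannot be told apart, because 0 arrays of RNA taken before the pull-down could be compared, and both stay open as hypotheses.

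Similarity of deviations from the group means fell with distance in sample number over the 16 pairs of a GnRH and a vehicle library, but did not pass on the tested probes (r = -0.410, exact permutation test within groups, one-sided, p = 0.0868), whereas the first form, over all 28 pairs, had passed (r = -0.435, p = 0.0177), with centring inside groups as part of its value. The 12130 probes above background on no array, which were not among the tested probes, had a trend that passed in both forms (r = -0.669, same exact permutation test within groups, p = 0.00347; first form r = -0.342, p = 2.98e-04), in line with a technical effect of array or processing order as a hypothesis, though the 4 pairs at distance 1 are those of equal replicate number, so processing by replicate stays open beside it. Median signal also fell with sample number (Pearson's r = -0.941, exact permutation p = 4.96e-04, adjusted over 4 relations 9.92e-04; Spearman's rho = -0.905, exact permutation p = 0.00456, adjusted 0.00913; r = -0.911 without the 2 libraries farthest from the median sample number), but brightness as the whole cause was argued against on the probes above background on no array, where the partial correlation given the difference in median signal stayed at -0.554 (exact permutation p = 0.0451, and 0.0243 with residuals permuted), while on the tested probes, at -0.281 (p = 0.201 and 0.153; first form -0.321, p = 0.0671), it stays open. A shared culture behind equal replicate numbers stays open, since the mean correlation of the 4 pairs of equal number was 0.350 and 3 of the 24 ways of matching GnRH to vehicle libraries gave a mean at least as high (exact test, one-sided, p = 0.125). No biological explanation was tested.

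Samples far from the others in their group were found in 5 of 156 groups of values tested, where chance gives about 1 in 20. Itpkc in GnRH replicate 4 stood at a log2 signal of 9.64, against 8.17 to 8.41 in the other GnRH libraries. Pmvk in GnRH replicate 4 stood at 7.07, against 5.99 to 6.16. Atf3 in vehicle replicate 2 stood at 4.39, against 4.29 to 4.30, all below background. The upper quartile of raw signal was 106.5 in GnRH replicate 1, against 88.9 to 90.1 in the other GnRH libraries. The highest raw signal was 8423 in vehicle replicate 4, that of Gnrhr, against 13198 to 13864 in the other vehicle libraries.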

How the results depend on the processing

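The runs of sample numbers as a block and the lists without immediate early genes were chosen after the data were seen. No result past the threshold changed direction in any alternative; a result past it in neither setting is given no direction. The 30 called probes kept a positive change in each alternative that tested them, and 14 of them, from 12 genes, stayed called in every one of the 24 alternatives that tested them. The count of higher probes, 30 (27 genes), became 14 (12) with no filter on dim probes, 46 (41) with array weights and 47 (42) with the replicate block and array weights, and ranged from 16 to 26 (14 to 23) with 1 library left out; leaving out a GnRH library also leaves 26 of the 30 probes tested. The count of lower probes, 0, became 4 (3 genes) with array weights and ranged from 0 to 1 (0 to 1) with 1 library left out, the 1 without vehicle replicate 1. The number of lists past the threshold, 6, became 3 with no background correction, 3 with no filter, 3 with 1 probe per gene, 1 with an estimated correlation, 2 with fry and 2 without the immediate early genes, and ranged from 4 to 6 with 1 library left out. For the lists that lost their call, adjusted p-values follow. With no background correction they were 0.0660 for secretory granule genes, 0.0505 for known targets and 0.0515 for translation factors; with no filter 0.302, 0.568 and 0.302; with 1 probe per gene 0.0977, 0.139 and 0.0977; with fry 0.221, 0.221 and 0.712; without the immediate early genes 0.0593, 0.271 and 0.0593. With an estimated correlation they were 0.269, 0.477 and 0.626, 0.0676 for MAP kinase and calcium feedback genes and 0.463 for the unfolded protein response, which fry put at 0.315. Secretory granule genes also lost their call at an offset of 50 (0.0638), with the authors' values (0.0518) and with array weights (0.176), and translation factors with the replicate block and array weights (0.230) and with runs as a block (0.528). With 1 library left out, adjusted p-values ranged from 2.08e-85 to 2.79e-42 for immediate early genes, 2.04e-06 to 0.00193 for feedback genes, 0.00102 to 0.292 for known targets, 0.0121 to 0.226 for secretory granule genes, 0.00149 to 0.551 for translation factors and 8.89e-07 to 0.0418 for the unfolded protein response. Secretory granule genes and translation factors share 0 members with the immediate early genes. Their unadjusted camera p-values, 0.0158 and 0.0152, were the same without those genes. Only the adjustment over lists moved, because the immediate early list itself was left out and could not be counted there. For the other changes the cause was not tested.

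Equal replicate numbers were not taken to pair the samples: correlations of deviations were 0.723, -0.227, 0.256 and 0.649 for numbers 1 to 4, so 1 pair fell short of 0.1. With the replicate block 43 probes were higher and 0 lower, and 5 of 8 libraries correlated best with their own number in the other group, a hint from the data and not from the design. The remaining settings with all 8 libraries gave 24 to 34 higher probes, apart from 20 among probes detected on all 8 arrays and 45 with runs as a block. Among named genes and other lists, 34 results lost their call, 25 gained one and 2, Lhb and Fshb under median scaling, moved while below background. Signal over background limits these arrays: the probes of genes such as Lhb, Nr4a1 and Myc were too dim to be tested. Those of Eef1a1, Rpl6 and Rplp2 were also above background on no array, so a dim probe does not show that its transcript was scarce. Slide as a block was not run, since no slide is given in the sources used here.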

Other observations

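Within the families of immediate early transcription factors the members differed in their measured change; Egr3, Fosl1, Jund, Nr4a1 and Ier2 were chosen for naming after their values were seen. Egr1, Egr2 and Egr4 rose, while Egr3 stood at -0.25 ± 0.20 (SE, limma adjusted p = 1.00) and between -0.26 and -0.12 over 5 scalings, with a signal above background on 1 GnRH and 4 vehicle arrays, near the floor. Fos and Fosb rose, while Fosl1 was above background on 2 GnRH and 0 vehicle arrays and was not tested. Jun and Junb rose, while Jund stood at 0.58 ± 0.28 (limma adjusted p = 1.00). Nr4a1 and Ier2, immediate early genes in many cells, were not above background on any array. Differences between family members were not tested.

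Of the 27 called genes 6 stood on no list, and apart from Npas4 and Itpkc they were chosen after their values were seen. Both probes of Irak2, a kinase of interleukin-1 and Toll-like receptor signalling, rose, by 1.84 ± 0.20 and 1.70 ± 0.17 on the log2 scale (SE, n = 4 libraries per group). Nfkbiz, an atypical inhibitor of NF-kappaB, rose by 1.30 ± 0.18, and Zfp184, a zinc finger protein, by 1.62 ± 0.27; these stayed called in 20 and 14 of 24 alternative settings. AU015228, a gene with a placeholder name, rose by 2.07 ± 0.14 and was above background on 1 of 4 vehicle arrays.

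With runs of sample numbers as a block, 15 further probes were higher, among them Ppp1r15a, Klf2, 2 Crem probes, Irf2bpl, Coq10b, Stbd1 and Tgif1. Without the block these were the nearest of the 15 to the threshold. Klf2 stood at 1.41 ± 0.27 (limma adjusted p = 0.0929), Tgif1 at 0.99 ± 0.18 (0.0612) and Stbd1 at 0.94 ± 0.16 (0.0503). The others lay far from it, the nearest being Rin2 at 0.70 ± 0.18 (limma adjusted p = 0.604), with Polg2 at 0.84 ± 0.24 (0.822). These genes other than Ppp1r15a were chosen after their values were seen. The runs were read from these data, so the block favours such calls.

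The 3 leading components of the tested probes held 36.9%, 30.9% and 12.4% of the variance, and the third separated the GnRH from the vehicle libraries. Treatment accounted for 15.1% of the variance over all tested probes, where chance gives 14.3%, and replicate number for 58.9%, where chance gives 42.9%. The runs of sample numbers accounted for 57.8%, which has no chance value here because they were read from these data.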
